A study of Mus musculus with 67 samples.

How the data were processed

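Transcript levels were measured in aorta, heart, kidney and liver of male mice of 3 inbred strains, hypertensive BPH/2J, normotensive BPN/3J and hypotensive BPL/1J, on 67 single-colour arrays. Per the labels, the mice were 12 weeks old, the aorta ran from its root to the left renal artery, and tissues of 5 mice per strain were collected independently. Heart, kidney and liver RNA was amplified by reverse transcription and in vitro transcription and hybridised as cRNA, while aorta RNA was amplified with a NuGEN Ovation protocol and hybridised as cDNA, per the labels' protocols. Samples went through these steps side by side in plates. No plate, scan date or other batch was given, so batches could not be tested. The aorta groups hold 9 BPH, 5 BPN and 9 BPL arrays against the 5 mice per strain of the design text, and the labels do not tie arrays to animals. The p-values therefore measure only the spread between arrays, part of which may be technical.

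The deposited values are an intensity per probe set, normalised with RMA per the submitters' processing notes and design text. RMA corrects the background, sets the arrays to a common distribution and summarises the probes of a probe set. The values ran from 1.8 to 22648, so they were read as linear intensities and log2 was taken with a pseudocount of 0. Array medians lay between 25.3 and 26.6 in aorta, 24.6 and 26.3 in heart, 29.8 and 31.5 in kidney, and 13.6 and 14.4 in liver. Quantiles were close to equal within a tissue and differed between tissues, so levels were compared only within a tissue. A common distribution also removes any difference in total transcript amount between strains. Detection calls were not given, and a probe set of low intensity may lie at background.

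The table holds 38385 probe sets. In the platform annotation 24478 had 1 gene symbol and 65 had several, while 13842 were not listed and are unnamed here. The named probe sets covered 19147 genes, 3958 of them with more than 1 probe set. Entrez identifiers of 24237 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which served only for current symbols and for neighbouring genes. The array's own genome build was not given, so no coordinates are reported. List genes without a named probe set were not analysed.

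Each tissue was fitted with limma 3.58.1 in R 4.3.3, with a mean per strain and a moderated variance (lmFit and eBayes) over all arrays of that tissue. Adjusted p-values are Benjamini-Hochberg values over all 38385 probe sets of a contrast, and a probe set was called below 0.05. A probe set was called graded with strain pressure when BPH differed from BPN and BPN from BPL in the same direction. Because both contrasts share the BPN arrays, these counts are given with 100 simulations of unchanged groups, with the overlap of independent lists and with counts after splitting the BPN arrays. Differences common to the tissues were probe sets called in the same direction in each tissue's fit. Whether the BPH against BPN difference itself differed between a pair of tissues was tested as an interaction in a joint limma fit of all 12 groups of tissue and strain.

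Lists of genes were fixed before the data were examined, as were the comparisons, tests and rule for named genes. Every tissue had lists for renin-angiotensin, sympathetic and adrenergic, circadian clock, oxidant and antioxidant enzymes, macrophage markers, lymphocyte markers, interferon response, antigen presentation, extracellular matrix, red blood cell markers, immediate early genes and adipocyte markers. Aorta added smooth muscle contractile, endothelial, vasoactive signalling and striated muscle lists. Heart added hypertrophy and fetal cardiac genes, fatty acid oxidation, ion channels and calcium handling, and atrial markers. Kidney added tubular sodium transport, proximal tubule, collecting duct, podocyte, arachidonate and epoxide metabolism, tubular injury and adrenal lists. Liver added cholesterol synthesis and uptake, bile acid synthesis and transport, fatty acid synthesis, fatty acid oxidation and ketogenesis, xenobiotic metabolism, male-biased and female-biased genes, acute phase and bile duct lists. A list gene was its probe set of highest mean. Lists were tested against all other named genes, each by 1 probe set, with camera at a preset correlation of 0.01, adjusted over the lists of the tissue, and again with an estimated correlation. Members called were counted with adjustment over all probe sets and adjusted over the list alone.

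The genes named were, per tissue, the 6 largest increases and 6 largest decreases of BPH against BPN and 3 of each for BPL against BPN, among called genes whose arrays did not overlap between the strains. They also included 2 graded genes in each direction, a few fixed genes per tissue, up to 2 members of each list, and the 5 largest mean increases and decreases common to the 4 tissues. Some further list members were named after their values were seen.

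The procedure was tested on simulated data, with 50 probe sets changed at each of 4 fold sizes at the spread of the real arrays. For BPH against BPN, changes of 1.41-fold were recovered for 60% of probe sets in aorta, 92% in heart, 68% in kidney and 70% in liver, and changes of 2-fold for 98%, 100%, 98% and 100%. Of 37985 unchanged probe sets, 15, 18, 23 and 19 were called in these tissues. An interaction of log2 1 between heart and kidney was recovered for 172 of 200 probe sets.

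The alternatives were median centring, renewed quantile normalisation, a filter at the median level, a trended and robust variance, array weights, 1 probe set per gene, the joint fit of all groups, a fit of the 2 strains compared, the replicate number as a block, and leaving out each array in turn. Added after seeing the data were fits without 3 kidney arrays that held adrenal transcripts, fits with marker levels as covariates, and a joint fit without aorta. Lists of B cell and dendritic cell markers were also written after the antigen presentation result was seen. Same-numbered arrays were also checked for deviating together.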

Results

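Schlager's blood pressure lines were bred from the same mixed founders and give a mouse model of inherited hypertension, BPH/2J, with a normotensive line, BPN/3J, and a hypotensive line, BPL/1J. The systolic pressures stated for these strains were 142 ± 5 mmHg, 94 ± 6 mmHg and 69 ± 1.7 mmHg, with no word on the kind of error. Transcripts were measured in male mice of 12 weeks in aorta, the vessel that carries the raised pressure, and in heart, kidney and liver. The arrays numbered 9 BPH, 5 BPN and 9 BPL for aorta, 5 of each strain for heart and liver, and 5 BPH, 5 BPN and 4 BPL for kidney. Differences are log2 values ± standard error of the limma fit, levels are log2 intensities ± SD, p-values are adjusted over all probe sets, and genes said to rise or fall passed 0.05. Detection calls were not given, so no fold is given where the mean of a strain lies below the lower quartile of any array of its tissue. The split of called probe sets into higher and lower depends on how the arrays are scaled. The first 2 principal components separated the strains in each tissue, the first carrying 23.1% of the variance in aorta, 25% in heart, 24.4% in kidney and 24.1% in liver. Throughout, a strain comparison sets whole genomes against each other, so a difference belongs to the strain and not to its pressure alone.

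In aorta Thumpd1 differed most between BPH and BPN. This adaptor for tRNA acetylation stood at 10.45 ± 0.11 in 9 BPH arrays and 3.52 ± 0.45 in 5 BPN arrays (122-fold, log2 6.93 ± 0.15, adjusted p = 9.43e-21). Gabra3, a subunit of the GABA-A receptor, rose (75.2-fold, log2 6.23 ± 0.13, adjusted p = 4.64e-21), and Sphkap, an anchor for protein kinase A, rose (66.6-fold, log2 6.06 ± 0.24, adjusted p = 6.91e-16). The ubiquitin ligase Mid1 (37-fold, log2 5.21 ± 0.33, adjusted p = 1.27e-11), the neurexin ligand Nxph1 (log2 4.97 ± 0.25, adjusted p = 9.18e-14) and the phospholipase Gdpd3 (30.3-fold, log2 4.92 ± 0.20, adjusted p = 8.59e-16) followed. Chad, a matrix protein of cartilage, fell from 9.92 ± 0.25 to 4.31 ± 0.25 (48.7-fold, log2 -5.61 ± 0.15, adjusted p = 2.21e-19). Emilin2, a glycoprotein of elastic fibres, fell too (29.2-fold, log2 -4.87 ± 0.17, adjusted p = 7.6e-17), as did the immune checkpoint ligand Vtcn1 (-4.46 ± 0.16), Tmem267 (-4.36 ± 0.12), the apoptosis gene Pmaip1 (-4.21 ± 0.19) and Ccdc42 (-3.72 ± 0.13). Arrays of the 2 strains did not overlap for any of these genes. In total 3513 probe sets of 2497 genes differed, 1708 higher and 1805 lower in BPH, and 690 of them by 2-fold or more. A joint fit of all 12 groups called 7152 probe sets.

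Few contractile genes of aortic smooth muscle passed the test between BPH and BPN. Of 15 contractile genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone), the 1 being Synpo2, an actin-associated protein (-0.27 ± 0.07, camera adjusted p = 0.286), while Acta2 (-0.02 ± 0.06, adjusted p = 0.912) and Myh11 (0.01 ± 0.06, adjusted p = 0.974) did not pass. Receptors for vasoactive peptides and their cyclic nucleotide partners moved in both directions. Npr1, the guanylyl cyclase receptor of atrial natriuretic peptide, rose (2.31 ± 0.13), with Pde5a, which degrades cGMP (0.88 ± 0.19), and the nitric oxide receptor subunit Gucy1a1 (0.21 ± 0.06). Ece1, which makes endothelin, fell (-0.74 ± 0.14), as did the natriuretic peptide clearance receptor Npr3 (-0.56 ± 0.11). In this vasoactive signalling list of 21 genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.916). Among 13 endothelial markers 1 rose and 0 fell (1 and 0 adjusted over the list alone), the nitric oxide synthase Nos3 (0.34 ± 0.11, adjusted p = 0.0435, camera adjusted p = 0.612), a call lost without any 1 of 14 arrays (log2 0.32 and adjusted p = 0.103 at its highest). Of 11 renin-angiotensin genes 0 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0497, and 0.235 with an estimated correlation). Called were Ace (-0.31 ± 0.09), Agtr1b (-0.60 ± 0.16) and Agtr2 (-0.41 ± 0.12). Agtr1a, the main vascular angiotensin receptor, gave -0.07 ± 0.15, adjusted p = 0.879. Agtr1b was not called without BPN 11 (log2 -0.54, adjusted p = 0.0568), and Agtr2 was not called without any 1 of 7 arrays (log2 -0.28 and adjusted p = 0.163 at its highest).

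Several matrix and immune transcripts were lower in BPH aorta. Of 24 extracellular matrix genes 0 rose and 7 fell (0 and 12 adjusted over the list alone, camera adjusted p = 1.09e-05, and 0.219 with an estimated correlation), led by Thbs1, an activator of TGF-beta (-2.38 ± 0.23), Tgfb2 (-1.02 ± 0.10), the collagenase Mmp2 (-0.77 ± 0.15) and the collagen crosslinker Lox (-0.57 ± 0.10). Antigen presentation showed 7 of 16 genes lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 2.28e-05, and 0.235 with an estimated correlation), among them the class II chain H2-Ab1 (-1.69 ± 0.32, adjusted p = 0.00054) and its chaperone Cd74 (-1.32 ± 0.33, adjusted p = 0.00889). Of 11 lymphocyte markers 0 rose and 5 fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.00708, and 0.48 with an estimated correlation). These were the T-cell chains Cd3e (-1.12 ± 0.27), Cd3g (-0.74 ± 0.24) and Cd3d (-0.70 ± 0.21) and the B-cell genes Ms4a1 (-1.40 ± 0.44) and Cd79b (-1.11 ± 0.35). Cd3d was not called without BPN 11, 12 or 14 (log2 -0.53 and adjusted p = 0.127 at its highest). Macrophage markers gave 0 limma calls of 13, with 6 at unadjusted p under 0.05 (camera adjusted p = 0.0649), and of 13 interferon genes 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.207), the 1 being Gbp3 (-0.38 ± 0.11), not called without any 1 of 6 arrays (log2 -0.33 and adjusted p = 0.105 at its highest).

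Of 11 sympathetic genes 0 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.273). The called genes were the noradrenaline transporter Slc6a2 (-0.84 ± 0.23), the decarboxylase Ddc (-0.71 ± 0.18) and the receptor kinase Grk5 (-0.37 ± 0.07). Ddc was not called without BPN 14 (log2 -0.63, adjusted p = 0.0505). Among 17 clock genes 0 rose and 3 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.0497, and 0.235 with an estimated correlation). They were Nr1d1 (-1.31 ± 0.25), Nr1d2 (-1.07 ± 0.20) and Tef (-0.86 ± 0.22). Of 22 oxidant and antioxidant genes 4 rose and 0 fell (5 and 1 adjusted over the list alone). Called were the peroxiredoxin Prdx1 (0.49 ± 0.08), Gsr (0.57 ± 0.10), Gclc (0.56 ± 0.12) and the oxidase subunit Cyba (0.33 ± 0.08). The list median was -0.0164 and its mean 0.0399, of different sign (camera adjusted p = 0.353). Of 14 immediate early genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.916). Egr2 (1.21 ± 0.36) and Egr1 (0.62 ± 0.16) rose and Ier3 (-0.50 ± 0.15) fell. Egr1 was not called without BPN 15 (log2 0.49, adjusted p = 0.0554) or in the joint fit (adjusted p = 0.326), and Ier3 was not called without BPH 7 or BPN 12 or 13 (log2 -0.36 and adjusted p = 0.143 at its highest). Of 10 adipocyte markers 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.0641), the uncoupling protein of brown fat Ucp1 rising (1.37 ± 0.24, adjusted p = 0.000202, but adjusted p = 0.0843 in the joint fit) and leptin, Lep, falling (-1.53 ± 0.38, adjusted p = 0.00916), the latter not called without BPN 11 (log2 -1.19, adjusted p = 0.0516). Of 14 striated muscle markers 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.353). Called were Tnnt2 (1.84 ± 0.11) and Ckm (-0.88 ± 0.24), with Ckm not called without BPN 15 (log2 -0.82, adjusted p = 0.0538). Red blood cell markers gave 0 limma calls of 4, with 1 at unadjusted p under 0.05 (camera adjusted p = 0.241).

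In hypotensive BPL aorta extracellular matrix genes fell relative to BPN, 14 of 24 with 0 rising (17 and 0 adjusted over the list alone, camera adjusted p = 2.97e-12, adjusted p = 0.0111 with an estimated correlation). Immediate early genes fell as 7 of 14 (9 adjusted over the list alone, camera adjusted p = 2.73e-06, and 0.105 with an estimated correlation), among them Atf3 (-2.69 ± 0.50), the orphan receptor Nr4a1 (-2.20 ± 0.35) and Fos (-1.87 ± 0.39). In the contractile list 0 rose and 3 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.000209, and 0.105 with an estimated correlation), with Actg2 (-1.05 ± 0.08), Des (-0.72 ± 0.17) and Tagln (-0.28 ± 0.07). Of 10 adipocyte markers 1 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0315, and 0.599 with an estimated correlation), with a list median of 0.482. Their mean level was 1.15 below the aorta mean in BPN array 14 and at most 0.36 below it in the other BPN arrays. Of the single genes, A530053G22Rik (6.40 ± 0.25), Gabra3 (6.16 ± 0.13) and the class I gene H2-Q10 (5.75 ± 0.24) rose most in 9 BPL against 5 BPN arrays, and the class II gene H2-Ea (-5.08 ± 0.34), the interferon-inducible Ifi202b (-5.07 ± 0.20) and the matrix gene Coch (-5.03 ± 0.18) fell most. In all 3971 probe sets differed, 1974 higher and 1997 lower in BPL, and the joint fit called 7431.

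Ordered by strain pressure, some aortic genes ran from BPH through BPN to BPL. The potassium channel Kcnk1 stood at 10.08 ± 0.21, 6.03 ± 0.34 and 3.45 ± 0.39 in the 3 strains and Ptchd4 at 7.89 ± 0.30, 3.45 ± 0.23 and 2.59 ± 0.23. The protease-like gene Prss35 (4.17 ± 0.43, 4.82 ± 0.21, 8.91 ± 0.16) and the GTPase Gbp2b (4.40 ± 0.38, 5.03 ± 0.22, 8.77 ± 0.11) ran the other way. Such graded probe sets numbered 102, below the 182 of independent lists and above the 0 of unchanged simulated groups, and split BPN arrays gave 36 to 54. Comparing BPH with BPL directly, 4231 probe sets differed, 2175 higher and 2056 lower in BPH, with 11 of 14 immediate early genes higher (camera adjusted p = 9.9e-07, and 0.154 with an estimated correlation). Graded counts were 67 without BPN replicate 13 and 270 in the joint fit. Between BPH and BPL it called 7890, against 2715 with 1 probe set per gene.

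In heart the phospholipase Gdpd3 rose (55-fold, log2 5.78 ± 0.10, adjusted p = 4.65e-17) between 5 BPH and 5 BPN arrays, followed by AA465934 (27.2-fold, log2 4.77 ± 0.06, adjusted p = 1.19e-18), Thumpd1 (log2 4.40 ± 0.06, adjusted p = 1.19e-18), the secreted factor Tafa2 (log2 3.99 ± 0.08, adjusted p = 4.35e-16), the matrix protein Spon1 (3.29 ± 0.09, adjusted p = 5.84e-14) and Hsd17b7, an enzyme of sterol synthesis (3.26 ± 0.08, adjusted p = 2.99e-15). Tmem267 fell (16.6-fold, log2 -4.06 ± 0.09, adjusted p = 2.97e-15), with the cytokine Il15 (9.94-fold, log2 -3.31 ± 0.07, adjusted p = 1.52e-15), Smim14 (-2.93 ± 0.07), the autophagy protease Atg4a (-2.92 ± 0.07), Rab6b (-2.82 ± 0.15) and Gm4841 (-2.48 ± 0.59). No BPH array overlapped a BPN array for these genes. With the probe set of highest mean, however, Spon1 read -1.28 (adjusted p = 2.36e-09) and Smim14 read 0.11. In total 2695 probe sets differed, 1346 higher and 1349 lower, of which 227 by 2-fold or more, and a joint fit of all groups called 1530.

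Natriuretic peptides and myosins, the usual transcripts of cardiac load, did not pass the test between BPH and BPN hearts: Nppa gave -0.12 ± 0.14, adjusted p = 0.751, Nppb -0.35 ± 0.13, adjusted p = 0.131, Myh6 -0.06 ± 0.05, adjusted p = 0.597 and Myh7 0.16 ± 0.11, adjusted p = 0.52. Nppb passed without BPH 3 (adjusted p = 0.0328) and with array weights (adjusted p = 0.0469). In the hypertrophy and fetal gene list of 14, 2 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.733). Ankrd1, a stretch-responsive sarcomere protein, rose (1.23 ± 0.08), and the calcineurin regulator Rcan1 rose (0.48 ± 0.12), while Acta2 (-0.43 ± 0.10, adjusted p = 0.00942), Xirp2 (-0.34 ± 0.07) and Acta1 (-0.30 ± 0.09) fell. The Acta1 call was lost without any 1 of 11 arrays (log2 -0.27 and adjusted p = 0.111 at its highest). Of 21 channel and calcium genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.952), with the calcium channel subunit Cacna2d1 (0.58 ± 0.08) and the sodium-calcium exchanger Slc8a1 (0.30 ± 0.06) higher and the transient outward channel Kcnd3 (-0.30 ± 0.07) lower. The median of that list was -0.0191 and the mean -0.0412, while the test pointed up. Of 16 fatty acid oxidation genes 0 rose and 2 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0263, and 0.488 with an estimated correlation). Those called were the nuclear receptor Ppara (-0.54 ± 0.07) and the carnitine carrier Slc25a20 (-0.22 ± 0.06), the latter not called without BPH 5 or BPN 3 (log2 -0.20 and adjusted p = 0.0523 at its highest). Of 9 atrial markers 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0172, and 0.488 with an estimated correlation). These were the atrial connexin Gja5 (-0.74 ± 0.19) and Tbx5 (-0.38 ± 0.10). Gja5 was not called without any 1 of 5 arrays (log2 -0.69 and adjusted p = 0.059 at its highest), and Tbx5 was not called without BPH 2 or 4 or BPN 1 or 4 (log2 -0.36 and adjusted p = 0.0604 at its highest). The joint fit did not call Ppara, Tbx5, Xirp2, Slc25a20 and Acta1 (adjusted p = 0.146 to 0.993). Atrial marker levels were low in BPH arrays 2, 4 and 5 and in BPL array 2.

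Antigen presentation genes were lower in BPH heart, with 13 of 16 genes falling and 0 rising (15 and 0 adjusted over the list alone, camera adjusted p = 9.38e-15, and 0.249 with an estimated correlation). H2-Ab1 fell (-1.53 ± 0.19), Cd74 (-1.31 ± 0.16) and B2m, the light chain of class I, (-0.67 ± 0.12). Of 13 macrophage markers 0 rose and 5 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.00547, and 0.488 with an estimated correlation). The called genes were C1qb (-0.74 ± 0.12), Adgre1 (-0.70 ± 0.12), C1qc (-0.62 ± 0.10), Aif1 (-0.59 ± 0.12) and Cd163 (-0.33 ± 0.10). Macrophage marker levels were highest in BPN array 2 (0.53 above the heart mean, others at most 0.16), without which 4 were called. Of 13 interferon genes 0 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.0354, and 0.488 with an estimated correlation). They were Gbp3 (-0.75 ± 0.15) and Gbp2 (-0.71 ± 0.10). Lymphocyte markers gave 0 limma calls of 11, with 2 at unadjusted p under 0.05 (camera adjusted p = 0.81). Their mean level was 1.39 above the heart mean in BPH array 5 and between -0.26 and -0.06 in the other BPH arrays. Without that array the median change of the list moved from 0.167 to -0.142, with 0 calls.

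Mitochondrial superoxide dismutase, Sod2, fell (-1.06 ± 0.06, adjusted p = 3.32e-10) in BPH heart, and Prdx1 rose (1.16 ± 0.07, adjusted p = 4.25e-09). Of 22 oxidant and antioxidant genes 2 rose and 5 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.0627). Of 11 renin-angiotensin genes 0 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.395). Called were angiotensinogen, Agt (-0.57 ± 0.13, adjusted p = 0.0119), and the aminopeptidase Enpep (-0.89 ± 0.12), while Ace gave -0.10 ± 0.07. Of 11 sympathetic genes 0 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.195). Called were Ddc (-1.09 ± 0.14) and Grk5 (-0.53 ± 0.08). Of 24 matrix genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.299). Sparc (0.41 ± 0.09) rose, and Thbs1 (-0.70 ± 0.12) and Lum (-0.29 ± 0.08) fell.

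Of 17 clock genes in heart 0 rose and 3 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.43). Those called were Nr1d1 (-0.37 ± 0.10), Nr1d2 (-0.35 ± 0.09) and Dbp (-0.46 ± 0.13). Nr1d2 was not called without BPH 3 or BPN 1, 2 or 3 (log2 -0.30 and adjusted p = 0.0706 at its highest), and Dbp was not called without any 1 of 7 arrays (log2 -0.40 and adjusted p = 0.0964 at its highest). Of 4 red blood cell markers 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0509). Called were the heme enzyme Alas2 (0.68 ± 0.16, adjusted p = 0.0138, and 0.0541 in the joint fit) and Bpgm (0.44 ± 0.12), with Bpgm not called without any 1 of 6 arrays (log2 0.34 and adjusted p = 0.094 at its highest). Of 14 immediate early genes 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.918). These were Junb (0.52 ± 0.14) and Btg2 (0.43 ± 0.13). Junb was not called without any 1 of 7 arrays (log2 0.40 and adjusted p = 0.0897 at its highest), and Btg2 was not called without any 1 of 10 arrays (log2 0.35 and adjusted p = 0.137 at its highest). Of 10 adipocyte markers 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.0209, and 0.488 with an estimated correlation). The 1 called was the lipase Pnpla2 (-0.23 ± 0.06), not called without any 1 of 7 arrays (log2 -0.20 and adjusted p = 0.0882 at its highest). Bpgm, Btg2, Nr1d2, Dbp and Pnpla2 were not called in the joint fit (adjusted p = 0.0973 to 0.797).

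In BPL heart the actin regulator Fmn1 rose above BPN (4.47 ± 0.08), with Plet1os (3.80 ± 0.08) and Ptprn2 (3.26 ± 0.13) in 5 arrays of each strain, and Tmem267 (-3.90 ± 0.09), Ifi202b (-4.30 ± 0.17) and H2-Ea (-4.17 ± 0.17) fell. Ptprn2 read 0.03 with its probe set of highest mean. Antigen presentation fell as 13 of 16 (13 adjusted over the list alone, camera adjusted p = 5.65e-14, and 0.242 with an estimated correlation) and macrophage markers as 8 of 13 (9 adjusted over the list alone, camera adjusted p = 1.6e-05, and 0.242 with an estimated correlation). Nppb fell (-0.74 ± 0.13, adjusted p = 0.000787). The channel partner Kcnip2 (0.75 ± 0.07) and the uncoupling protein Ucp3 (1.00 ± 0.14) rose. Adipocyte marker levels were above the heart mean in BPL arrays 1, 3, 4 and 5, by up to 1.17, and below it in BPL array 2. Altogether 3586 probe sets differed, 1591 higher and 1995 lower in BPL, and 1194 with marker levels as covariates or 1741 in the joint fit. The share higher was 44.4%, and 37.9% after median centring or 49.2% after renewed quantile normalization.

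Graded genes in heart included the ATP synthase subunit Atp5g1 (5.37 ± 0.16, 4.05 ± 0.21 and 3.06 ± 0.24 in BPH, BPN and BPL) and the kinesin Kif5c (6.94 ± 0.15, 5.09 ± 0.09, 4.78 ± 0.16). Smim14 (6.61 ± 0.14, 9.54 ± 0.04, 9.78 ± 0.10) and Bcat2, which degrades branched-chain amino acids (8.41 ± 0.10, 10.30 ± 0.04, 10.53 ± 0.10), ran the other way. By the probe set of highest mean the BPH to BPL difference was -0.09 for Atp5g1 and 0.15 for Smim14. Graded probe sets numbered 111 (126 from independent lists, 0 simulated, 35 to 40 with BPN arrays split). BPH and BPL hearts differed in 3288 probe sets, 1763 higher and 1525 lower in BPH, and adipocyte markers fell as 6 of 10 (7 adjusted over the list alone, camera adjusted p = 0.000168, and 0.392 with an estimated correlation). The joint fit called 1832 probe sets between BPH and BPL and 41 graded ones, and marker covariates left 1014 and 28.

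In kidney Angptl7, a secreted angiopoietin-like protein, rose (40.4-fold, log2 5.34 ± 0.16, adjusted p = 6.32e-13) in 5 BPH against 5 BPN arrays. Hdc, which makes histamine, rose (27.1-fold, log2 4.76 ± 0.09, adjusted p = 1.56e-15), Thumpd1 (14.3-fold, log2 3.83 ± 0.11, adjusted p = 7.84e-13), the carboxypeptidase Folh1 (log2 3.72 ± 0.08, adjusted p = 1.77e-14), the carbonyl reductase Cbr2 (11.3-fold, log2 3.50 ± 0.11, adjusted p = 1.91e-12) and Ankrd33b (10.6-fold, log2 3.41 ± 0.08, adjusted p = 6.05e-14). Tmem267 fell (log2 -6.36 ± 0.09, adjusted p = 2.49e-17), followed by the protease inhibitor Spink6 (log2 -4.90 ± 0.11, adjusted p = 1.66e-14), 4930481A15Rik (-3.83 ± 0.14), Atg4a (-3.23 ± 0.06), the progesterone-degrading Akr1c18 (-3.20 ± 0.14) and Smim14 (-2.80 ± 0.09). Arrays of the 2 strains did not overlap for these genes. With the probe set of highest mean Folh1 read -0.98 and Smim14 read 0 (adjusted p = 0.999). The comparison called 2706 probe sets, 1404 higher and 1302 lower in BPH, and 258 by 2-fold or more.

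Genes of distal sodium transport were among those higher in BPH kidney. Of 23 genes of tubular sodium transport and its regulators 8 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.00419, and 0.322 with an estimated correlation). The 3 subunits of the epithelial sodium channel rose, Scnn1a (0.33 ± 0.06), Scnn1b (0.48 ± 0.07) and Scnn1g (0.33 ± 0.07), along with the mineralocorticoid receptor Nr3c2 (0.34 ± 0.06) and the kinase Wnk4 (0.29 ± 0.09). The thiazide-sensitive cotransporter Slc12a3 rose (0.33 ± 0.08, adjusted p = 0.0194), not called without BPN 4 (log2 0.29, adjusted p = 0.0542). Of 12 collecting duct markers 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.000127, and 0.135 with an estimated correlation), including the intercalated cell genes Foxi1 (0.60 ± 0.09), Atp6v0d2 (0.64 ± 0.07) and pendrin, Slc26a4 (0.38 ± 0.06). Of 7 podocyte markers 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0015, and 0.135 with an estimated correlation). The called genes were Cdkn1c (0.63 ± 0.08) and Ptpro (0.37 ± 0.07, adjusted p = 0.00313, but adjusted p = 0.423 in the joint fit). Of 10 proximal tubule markers 0 rose and 1 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.00743, and 0.135 with an estimated correlation). This was the creatine enzyme Gatm (-0.62 ± 0.06). Of 11 renin-angiotensin genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.851). Neprilysin, Mme, rose (1.38 ± 0.08) and Ace (0.40 ± 0.11), while Mas1 (-0.85 ± 0.08), Enpep (-0.70 ± 0.11) and Agtr2 (-0.28 ± 0.08) fell, and Agt (-0.20 ± 0.19, adjusted p = 0.686) and Agtr1a (-0.03 ± 0.07, adjusted p = 0.915) did not pass. The Ace call was lost without any 1 of 6 arrays (log2 0.34 and adjusted p = 0.095 at its highest). Without the 3 arrays that held adrenal transcripts, Ace (adjusted p = 0.101) and Slc12a3 (adjusted p = 0.0865) were not called, nor was Slc12a3 in the joint fit (adjusted p = 0.277).

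Antigen presentation genes were lower in BPH kidney, with 12 of 16 falling and 0 rising (14 and 0 adjusted over the list alone, camera adjusted p = 5.88e-12, and 0.135 with an estimated correlation). H2-Ab1 fell (-1.55 ± 0.18, adjusted p = 2.38e-05) and Cd74 (-1.02 ± 0.20, adjusted p = 0.0037). Of 13 macrophage markers 0 rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.000112, and 0.135 with an estimated correlation). They were C1qb (-0.99 ± 0.14), Adgre1 (-0.90 ± 0.17), C1qc (-0.71 ± 0.14) and Aif1 (-0.51 ± 0.13). Of 11 lymphocyte markers 0 rose and 2 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0448, and 0.471 with an estimated correlation). Those called were Cd3g (-0.45 ± 0.12) and Cd3d (-0.43 ± 0.12). Cd3g was not called without any 1 of 7 arrays (log2 -0.37 and adjusted p = 0.0911 at its highest), and Cd3d was not called without any 1 of 11 arrays (log2 -0.36 and adjusted p = 0.116 at its highest). Of 13 interferon genes 1 rose and 3 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.0448, and 0.346 with an estimated correlation). Cxcl10 (-0.69 ± 0.19), Gbp2 (-0.63 ± 0.13) and Rsad2 (-0.33 ± 0.09) fell and Ifit2 (0.31 ± 0.08) rose, the last not called without any 1 of 6 arrays (log2 0.26 and adjusted p = 0.0847 at its highest). Cd3g and Cd3d were not called in the joint fit (adjusted p = 0.73 and 0.675), nor Cd3d and Ifit2 without the 3 arrays that held adrenal transcripts (0.193 and 0.151).

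In the redox group of kidney Prdx1 (0.86 ± 0.09) and Nqo1 (0.38 ± 0.07) rose and Sod2 (-0.83 ± 0.06) and Cybb (-0.44 ± 0.07) fell. Of 22 genes of this list 2 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.945). Of 13 arachidonate and epoxide genes 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.463). These were the epoxygenase Cyp2j6 (0.49 ± 0.08) and Cyp4a14 (0.31 ± 0.07). Of 11 tubular injury genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.525). Clu (0.63 ± 0.10) and Krt18 (0.38 ± 0.09) rose and Vcam1 (-0.44 ± 0.12) fell. In the joint fit Cyp4a14 (adjusted p = 0.18) and Krt18 (adjusted p = 0.321) were not called, nor was Cyp4a14 without the 3 arrays that held adrenal transcripts (adjusted p = 0.072). Of 24 matrix genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.651). The gene was Tgfb2 (0.63 ± 0.07). Of 11 sympathetic genes 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.0922). The 1 called was Ddc (-0.62 ± 0.08). Of 4 red blood cell markers 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.489), the anion exchanger Slc4a1 (0.55 ± 0.09).

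Of 17 clock genes in kidney 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.489). This was Nr1d2 (-0.48 ± 0.13), not called without any 1 of 5 arrays (log2 -0.38 and adjusted p = 0.0822 at its highest) or in the joint fit (adjusted p = 0.123). Limma called 0 of 14 immediate early genes (3 at unadjusted p under 0.05, camera adjusted p = 0.851) and 0 of 10 adipocyte markers (0, camera adjusted p = 0.841). It also called 0 of 12 adrenal markers, with 8 at unadjusted p under 0.05 (camera adjusted p = 0.00142, and 0.471 with an estimated correlation). Those adrenal transcripts were carried by 3 arrays. The steroid hydroxylase Cyp11b1 stood between 219 and 344 in BPN arrays 4 and 5 and BPL array 1 and between 5.26 and 12.6 in the others, and the cholesterol carrier Star between 375 and 536 against 11.9 to 28.2.

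In BPL kidney angiotensinogen, Agt, fell (-3.64 ± 0.21, adjusted p = 3.41e-09) in 4 BPL against 5 BPN arrays, the lipid kinase Pik3c2g (-5.33 ± 0.10) and the transporter Mfsd4b5 (-5.12 ± 0.11, but -2.60 with its probe set of highest mean). Tmem267 fell further than these, by log2 -6.104 to -5.978 over the alternative fits. Tm4sf5 (4.37 ± 0.07), the defensin Defb26 (4.18 ± 0.08) and transthyretin, Ttr (4.16 ± 0.10), rose. Of 16 antigen presentation genes 0 rose and 6 fell (0 and 11 adjusted over the list alone, camera adjusted p = 2.41e-05, and 0.666 with an estimated correlation). In total 2396 probe sets differed, 1235 higher and 1161 lower in BPL.

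Against BPL directly, BPH kidney had 7 of 12 collecting duct markers higher (10 adjusted over the list alone, camera adjusted p = 1.12e-08, and 0.0979 with an estimated correlation) and 10 of 23 sodium transport genes higher (13 adjusted over the list alone, camera adjusted p = 6.05e-06, and 0.116 with an estimated correlation). Graded genes included Zmynd8, a chromatin reader (7.22 ± 0.19, 6.74 ± 0.18 and 4.96 ± 0.26 in BPH, BPN and BPL), and, in the reverse order, the calcium buffer Pvalb (6.91 ± 0.16, 7.38 ± 0.18, 8.85 ± 0.08) and the cathepsin Ctsl (11.07 ± 0.04, 11.71 ± 0.12, 12.99 ± 0.04). Zmynd8 read 0.05 between BPH and BPL with its probe set of highest mean. BPH and BPL differed in 2429 probe sets, 1206 higher and 1223 lower in BPH (49.7% higher, 41.6% after median centring). Graded probe sets numbered 61 (84.4 from independent lists, 0 simulated, 21 to 28 with BPN arrays split). The graded count was 93 with only the more abundant probe sets or with a trended and robust variance, 30 in the joint fit and 31 without the 3 arrays that held adrenal transcripts.

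In liver, genes of lipid synthesis fell between BPN and BPH. Of 15 fatty acid synthesis genes 0 rose and 8 fell (1 and 9 adjusted over the list alone, camera adjusted p = 7.46e-05, and 0.347 with an estimated correlation), among them fatty acid synthase, Fasn (-0.86 ± 0.16), the lipogenic regulator Thrsp (-1.06 ± 0.20), the carboxylase Acacb (-0.75 ± 0.17) and the desaturase Scd1 (-0.66 ± 0.16), the last not called without BPH 1 (log2 -0.54, adjusted p = 0.0523) or in the joint fit (adjusted p = 0.284). Of 15 cholesterol synthesis genes 0 rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.00346, and 0.59 with an estimated correlation). The called genes were Mvd (-0.89 ± 0.10), Hmgcs1 (-0.70 ± 0.09), Pmvk (-0.51 ± 0.08) and Fdps (-0.34 ± 0.08). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell (3.86-fold, log2 -1.95 ± 0.30, adjusted p = 0.000255). Of 16 bile acid genes 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.601). Of 16 fatty acid oxidation and ketogenesis genes 3 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0532). The fatty acid transporter Cd36 (1.00 ± 0.22), Bdh1 (0.27 ± 0.08) and Hadhb (0.26 ± 0.07) rose and Fgf21 (-0.94 ± 0.17) and Pdk4 (-0.56 ± 0.16) fell.

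Among single liver genes Gdpd3 rose (31.9-fold, log2 5.00 ± 0.16, adjusted p = 6.5e-14) in 5 BPH against 5 BPN arrays, with neprilysin, Mme (12.2-fold, log2 3.61 ± 0.18, adjusted p = 6.65e-11), Thumpd1 (11.9-fold, log2 3.58 ± 0.10, adjusted p = 2.19e-14), AA465934 (9.73-fold, log2 3.28 ± 0.08, adjusted p = 4.8e-15), Cyp4b1 (8.51-fold, log2 3.09 ± 0.10, adjusted p = 5.41e-14) and Cyp2c55 (7.8-fold, log2 2.96 ± 0.21, adjusted p = 1.35e-08). Tmem267 fell (log2 -5.10 ± 0.09, adjusted p = 4.45e-17), with the inflammasome regulator Nlrp12 (log2 -4.71 ± 0.15, adjusted p = 6.55e-14), 4930481A15Rik (16-fold, adjusted p = 7.27e-15), the sarcomere protein Myom2 (-3.80 ± 0.12), Itih5 (-3.77 ± 0.19) and Atg4a (-3.45 ± 0.11). Their arrays did not overlap between the strains. Of 11 renin-angiotensin genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.396), the 1 being Mme, and Agt gave 0.03 ± 0.08, adjusted p = 0.913. In total 2739 probe sets differed, 1261 higher and 1478 lower in BPH, and 265 by 2-fold or more.

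In BPH liver antigen presentation had 10 of 16 genes lower and 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 1.03e-09, and 0.108 with an estimated correlation), with H2-Ab1 at -1.35 ± 0.16 and Cd74 at -1.24 ± 0.14. Of 13 macrophage markers 0 rose and 6 fell (0 and 9 adjusted over the list alone, camera adjusted p = 3.03e-06, and 0.263 with an estimated correlation), including C1qb (-0.84 ± 0.08) and C1qc (-0.64 ± 0.08). Of 19 acute phase genes 0 rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0157, and 0.59 with an estimated correlation). They were Orm2 (-1.27 ± 0.21), Saa3 (-1.25 ± 0.18), Serpina3n (-0.96 ± 0.07) and Orm1 (-0.36 ± 0.08). Of 13 interferon genes 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.992). Those called were Gbp2 (-0.64 ± 0.12) and Gbp3 (-0.37 ± 0.10), the latter not called without any 1 of 9 arrays (log2 -0.33 and adjusted p = 0.0982 at its highest). Of 11 lymphocyte markers 0 rose and 1 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.604). The gene was Cd3g (-0.38 ± 0.11), not called without any 1 of 6 arrays (log2 -0.32 and adjusted p = 0.105 at its highest). Cd3g and Gbp3 were not called in the joint fit (adjusted p = 0.779 and 0.0836).

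Few detoxifying and sex-biased genes of liver passed the test over all probe sets. Of 18 xenobiotic metabolism genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0532). These were Cyp2c55 (2.96), Aldh1a1 (0.45 ± 0.07) and Sult1d1 (0.38 ± 0.11). Of 8 male-biased genes 0 rose and 1 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.00346, and 0.507 with an estimated correlation). The 1 called was the elongase Elovl3 (-1.28 ± 0.14). Of 11 female-biased genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.601), Cyp3a44 (0.29 ± 0.07) and the steroid hydroxylase Cyp17a1 (-2.31 ± 0.14). In the joint fit Aldh1a1 (adjusted p = 0.191) and Cyp3a44 (adjusted p = 0.0566) were not called. Of 22 oxidant and antioxidant genes 2 rose and 3 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.624). Prdx1 (1.04 ± 0.08) and Sod3 (0.67 ± 0.09) rose and Sod2 (-0.64 ± 0.07), Cyba (-0.39 ± 0.09) and Ncf4 (-0.34 ± 0.09) fell, while catalase, Cat, gave -0.04 ± 0.05, adjusted p = 0.764. Of 11 sympathetic genes 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.836). Called were Grk5 (-1.21 ± 0.12) and Ddc (-1.04 ± 0.10).

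Of 24 matrix genes in liver 1 rose and 2 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.77). Sparc (1.07 ± 0.09) rose and Lum (-0.68 ± 0.11) and Tgfb1 (-0.43 ± 0.10) fell. Of 14 immediate early genes 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.695). This was Jun (-1.19 ± 0.22). Of 17 clock genes 0 rose and 1 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.763), Nr1d1 (-0.68 ± 0.20, adjusted p = 0.05, just under the threshold), not called without any 1 of 12 arrays (log2 -0.53 and adjusted p = 0.142 at its highest) or in the joint fit (adjusted p = 0.0586). Limma called 0 of 4 red blood cell markers (0 at unadjusted p under 0.05, camera adjusted p = 0.992), 0 of 10 adipocyte markers (1, camera adjusted p = 0.992) and 0 of 6 bile duct markers (0, camera adjusted p = 0.604).

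Nat8f2, an N-acetyltransferase, fell in BPL liver from 11.48 ± 0.10 in 5 BPN arrays to 2.32 ± 0.08 in 5 BPL arrays (-9.16 ± 0.07, adjusted p = 6.51e-24), a mean below the lower quartile of every liver array. The glutathione transferase Gstp3 (5.25 ± 0.09), Ankrd33b (3.13 ± 0.10) and the bile acid-sensitive channel Asic5 (3.12 ± 0.13) rose. In total 2866 probe sets differed, 1446 higher and 1420 lower in BPL. Between BPH and BPL 2213 differed, 1028 higher and 1185 lower in BPH, with 11 of 15 cholesterol genes lower in BPH (13 adjusted over the list alone, camera adjusted p = 7.57e-11, and 0.315 with an estimated correlation). Graded genes included Mme (7.06 ± 0.15, 3.45 ± 0.12 and 2.72 ± 0.55 in BPH, BPN and BPL) and Zmynd8 (5.63 ± 0.13, 5.04 ± 0.33, 3.47 ± 0.32), and the reverse order held for Nlrp12 (2.70 ± 0.26, 7.41 ± 0.36, 8.05 ± 0.16) and Ugt3a1 (5.49 ± 0.26, 7.69 ± 0.28, 8.22 ± 0.18). Zmynd8 gave -0.40 between BPH and BPL with its probe set of highest mean. Graded probe sets numbered 62 (102 from independent lists, 0 simulated, 27 to 34 with BPN arrays split).

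A set of genes differed between BPH and BPN in the same direction in all 4 tissues. Thumpd1 rose by log2 3.58 to 6.93, and by their mean over the tissues Gdpd3 rose by 22.8-fold (2.34 to 5.78), AA465934 by 10-fold (2.45 to 4.77), the fatty acid hydroxylase Cyp4b1 by 8.74-fold (3.01 to 3.38) and Ankrd33b by 7.13-fold (2.04 to 3.41). Tmem267 fell by log2 -6.36 to -4.06, Atg4a 8.53-fold (-3.45 to -2.76), Smim14 6.7-fold (-3.27 to -1.98), the sulfatase Arsk 5.34-fold (-3.12 to -1.89) and the adhesion receptor Adgre5 4.27-fold (-2.71 to -1.75), each with an adjusted p no higher than 1.18e-08 in any tissue. Prdx1 rose and H2-Ab1 and Cd74 fell in each tissue. Such probe sets numbered 253 (120 higher, 133 lower) of 179 genes, against 0.155 from independent lists, while 5682 of 8104 called probe sets were called in 1 tissue. The counts were 218 for BPL against BPN (106 higher, 112 lower) and 273 for BPH against BPL (133 higher, 140 lower). With 1 probe set per gene they were 156, 137 and 178. By its probe set of highest mean Smim14 read -0.02 in aorta (adjusted p = 0.893), 0.11 in heart, 0 in kidney and -0.09 in liver (adjusted p = 0.564), and Arsk read 3.44 in aorta, 0.18 in heart, 0.44 in kidney and 0.13 in liver. Another probe set of Ankrd33b, above the median level, differed by a mean of 0.005 over the tissues.

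**Figure D1:**
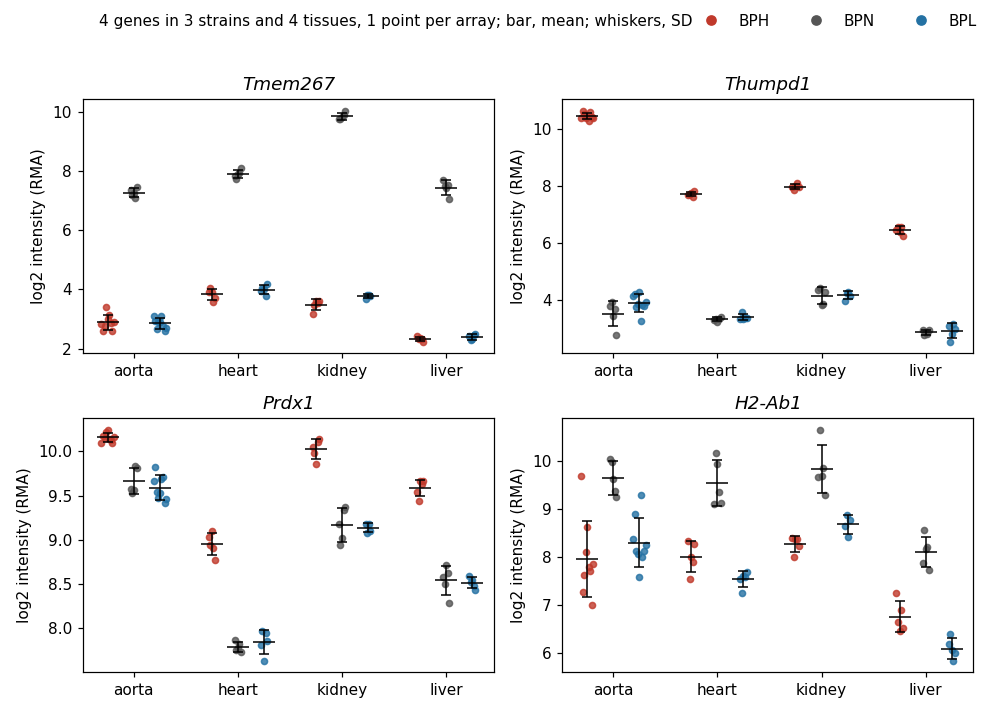
Log2 intensity of Tmem267, Thumpd1, Prdx1 and H2-Ab1 on each array, by tissue and strain, where the bar is the mean and the whiskers are the SD. Tmem267 and H2-Ab1 were lower and Thumpd1 and Prdx1 higher in BPH than in BPN in each tissue.

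Size, and at times direction, of the BPH to BPN difference depended on tissue. Tgfb2 fell in aorta (-1.02) and rose in kidney (0.63) (interaction adjusted p = 1.01e-16). In the joint fit the difference itself differed in 2798 probe sets between aorta and heart, 3484 between aorta and kidney and 4120 between aorta and liver. The numbers were 884 between heart and kidney, 1192 between heart and liver and 1019 between kidney and liver, and 2173, 2865 and 2146 with array weights. That fit shares 1 spread per probe set although the residual SD was 0.269 in aorta and 0.16 to 0.168 elsewhere. It can therefore call too many probe sets where aorta enters and too few elsewhere. Without aorta the last 3 counts were 1674, 2287 and 1850, so counts with and without aorta do not rank the tissues. Probe sets called in both tissues of a pair mostly shared their direction, 797 against 100 for heart and kidney and 562 against 175 for aorta and liver. Aorta had another labelling chemistry and more arrays, which enter these contrasts with the tissue.

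**Figure D2:**
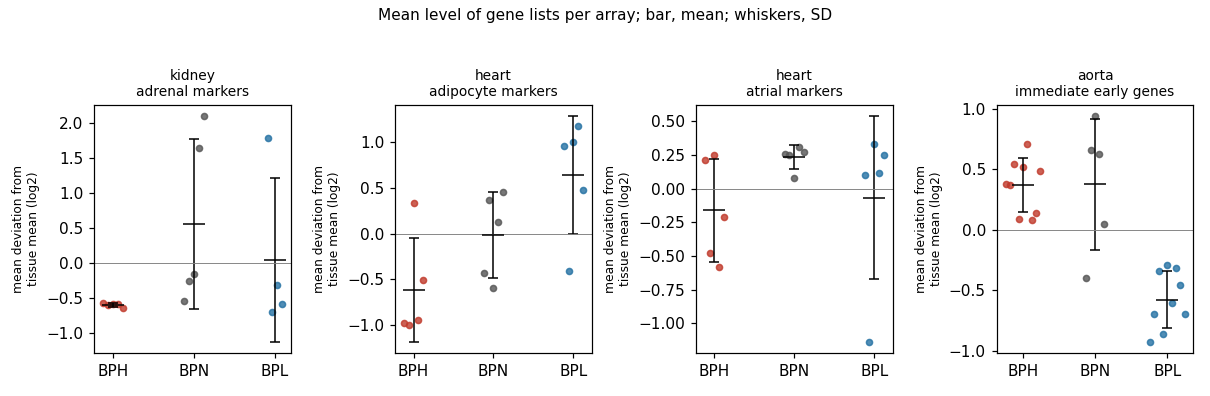
Mean deviation of marker lists from the tissue mean on each array, for adrenal markers in kidney, adipocyte and atrial markers in heart and immediate early genes in aorta, by strain. Adrenal markers stood high in 3 kidney arrays, and immediate early genes were below the tissue mean in every BPL aorta array.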

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

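Of the tests below, those of probe variants, whole-gene expression, leucocytes, B cells and dendritic cells, H2 probes and adipose tissue and all splits of the arrays were chosen only after the result was seen, while those of the second adrenal list and of adrenal tissue as a source were written down before their values were seen. Differences between BPH and BPN shared by the 4 tissues were weighed against sequence variants between the strains under the probes and against a difference of the whole gene. For 65 of the 179 genes another probe set with a mean above the median was present, and its difference divided by the shared one had a median of 0.022 (95% interval -0.0797 to 0.188), as variants under the probes predict. For 1150 genes called in 1 tissue alone the median ratio was 0.486 (0.442 to 0.527). Of the other probe sets 30.8% were called in the same direction in at least 2 tissues, 20 genes against 8 in the opposite direction and 17 called in no tissue, which leaves whole-gene expression open. Transcript variants of a gene could give such values too and were not tested.

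Antigen presentation genes lower in BPH were weighed against fewer macrophages and lymphocytes, against fewer B cells or dendritic cells and against variants under the H2 probes. The median change of 24 leucocyte markers was divided by that of H2-Aa, H2-Ab1, H2-Eb1 and Cd74. The ratio reached 0.24 at most, in aorta, and 0.0221 in heart (0.0999 without BPH array 5, high in lymphocyte markers). Low-level markers were kept, so a loss of macrophages or lymphocytes stays open. A loss of B cells was not excluded. In aorta 5 B cell markers above the median level of the tissue changed by a median of -1.11, which is 0.764 of the change of the 4 genes, and in the other tissues at most 2 such markers lay above that level. Dendritic cell markers reached 0.313, in aorta, and 0.166 or less elsewhere. Cd74, outside the H2 complex, was lower in 4 tissues and B2m in 2, which speaks against variants under H2 probes as the whole account. Variants under the probes of Cd74 itself could not be tested. Lower class II expression in BPH, or higher in BPN, stays open beside cell loss.

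Transcripts of other tissues in kidney and heart arrays were weighed as adrenal or adipose tissue. Of 12 first-list adrenal genes 9 were highest in kidney BPN arrays 4 and 5 and BPL array 1, as adrenal tissue predicts. Of a second list of 9 only 3 were (Mgarp, Chgb, Scg2), a number between the bounds set beforehand. The others leave adrenal tissue open, as Nr0b1, Dbh, Phox2a and Hand2 read at most 13.3 and Inha and Slc18a1 alike in all arrays. Without the 3 arrays the BPH to BPN differences of kidney kept a median ratio of 1.01 and their direction in 100% of probe sets. Adrenal tissue is excluded as the source only for the 70.1% still called. With marker levels as covariates the BPL to BPN differences of heart also kept a median ratio of 1.01. As the median standard error grew 1.5-fold, 31.4% were still called, and for the rest adipose tissue stays open. No biological explanation was tested for these arrays.

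A named gene stood out on a single array in 42 of 771 groups (5.45%), by the gap to the nearest array divided by the range of the group, and chance does so in about 1 in 20 groups. In aorta the single arrays far from the others of their strain were Kcnk1 in BPN array 14 (high, log2 6.61, ratio 0.714), Grk5 in BPN array 14 (high, log2 10.96, ratio 0.719), C1qb in BPH array 5 (high, log2 9.42, ratio 0.532) and Tgfb2 in BPH array 7 (low, log2 10.80, ratio 0.503). Also in aorta was Ece1 in BPH array 2 (high, log2 9.74, ratio 0.551). In heart the single arrays far from the others of their strain were Thumpd1 in BPL array 2 (high, log2 3.56, ratio 0.785), Gm4841 in BPL array 3 (high, log2 3.79, ratio 0.78), Atp5g1 in BPN array 1 (low, log2 3.69, ratio 0.732) and Bcat2 in BPH array 4 (low, log2 8.23, ratio 0.82). Further heart values were Nppa in BPL array 2 (low, log2 12.57, ratio 0.865), Ace in BPN array 5 (high, log2 7.49, ratio 0.835), Nr1d2 in BPH array 3 (low, log2 9.11, ratio 0.735) and Dbp in BPH array 5 (low, log2 5.22, ratio 0.769). Then came C1qb in BPN array 2 (high, log2 9.86, ratio 0.801), H2-Eb1 in BPL array 1 (high, log2 8.07, ratio 0.77), Thbs1 in BPH array 1 (low, log2 5.42, ratio 0.734) and Bpgm in BPN array 4 (high, log2 8.55, ratio 0.87). The last in heart were Bpgm in BPL array 4 (high, log2 9.02, ratio 0.79), Pnpla2 in BPH array 3 (high, log2 10.77, ratio 0.802) and Gja5 in BPL array 2 (low, log2 6.55, ratio 0.724). In kidney the single arrays far from the others of their strain were 4930481A15Rik in BPL array 1 (high, log2 4.27, ratio 0.973), Tm4sf5 in BPH array 4 (low, log2 4.27, ratio 0.793), Slc12a3 in BPL array 4 (low, log2 8.31, ratio 0.874) and Mme in BPN array 5 (low, log2 7.85, ratio 0.744). Also in kidney were H2-Aa in BPN array 2 (high, log2 8.49, ratio 0.725), Ier2 in BPN array 2 (high, log2 7.77, ratio 0.757), Pnpla2 in BPH array 3 (high, log2 9.40, ratio 0.773) and Cidea in BPN array 5 (low, log2 6.77, ratio 0.71). In liver the single arrays far from the others of their strain were AA465934 in BPH array 1 (low, log2 8.02, ratio 0.806), Cyp2c55 in BPL array 3 (high, log2 5.79, ratio 0.754), 4930481A15Rik in BPH array 2 (high, log2 3.92, ratio 0.78) and Atg4a in BPH array 2 (high, log2 4.15, ratio 0.865). Further liver values were Cyp7a1 in BPL array 2 (high, log2 8.39, ratio 0.733), Cat in BPL array 5 (low, log2 13.20, ratio 0.728), Grk5 in BPL array 3 (low, log2 5.25, ratio 0.777) and Ddc in BPH array 3 (high, log2 10.16, ratio 0.747). Next were Cd79b in BPH array 4 (high, log2 4.08, ratio 0.842), H2-DMa in BPH array 4 (high, log2 4.88, ratio 0.795), Hmgcs1 in BPH array 1 (high, log2 11.38, ratio 0.848) and C6 in BPL array 4 (low, log2 9.48, ratio 0.771). The last in liver were Cyp3a44 in BPN array 5 (low, log2 4.65, ratio 0.746) and Serpina3n in BPH array 1 (high, log2 10.63, ratio 0.81). Heart BPL array 2 and liver BPH array 1 each held 3 of these values.

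The BPH to BPN difference differed between tissues, by the interaction test, in 19 of 39 named genes tested in more than 1 tissue, each given here for the pair of smallest adjusted p. These were AA465934 (aorta 2.45, heart 4.77, adjusted p = 6.65e-24), Ace (heart -0.10, kidney 0.40, adjusted p = 0.0405), Adgre5 (aorta -2.71, kidney -1.75, adjusted p = 4.56e-10) and Ankrd33b (aorta 2.04, kidney 3.41, adjusted p = 1.68e-06). They included Arsk (aorta -3.12, heart -1.89, adjusted p = 2.59e-06), Atg4a (aorta -2.76, liver -3.45, adjusted p = 2.09e-05), Bpgm (aorta -0.46, heart 0.44, adjusted p = 0.00108) and Gdpd3 (heart 5.78, kidney 2.34, adjusted p = 3.05e-17). Also past the threshold were Grk5 (aorta -0.37, liver -1.21, adjusted p = 3.19e-08), Mas1 (kidney -0.85, liver -0.16, adjusted p = 0.000936), Mme (kidney 1.38, liver 3.61, adjusted p = 9.14e-07) and Nr1d2 (aorta -1.07, heart -0.35, adjusted p = 0.0433). The same held for Prdx1 (aorta 0.49, heart 1.16, adjusted p = 2.72e-06), Smim14 (aorta -1.98, liver -3.27, adjusted p = 5.01e-10), Sparc (heart 0.41, liver 1.07, adjusted p = 0.00012) and Tgfb2 (aorta -1.02, kidney 0.63, adjusted p = 1.01e-16). The list ended with Thbs1 (aorta -2.38, heart -0.70, adjusted p = 1.07e-06), Thumpd1 (aorta 6.93, liver 3.58, adjusted p = 6.45e-24) and Tmem267 (heart -4.06, kidney -6.36, adjusted p = 2.21e-18). Tmem267 in BPH kidney lay below the lower quartile of the arrays, so the size of its fall there is uncertain.

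Chance was tested with 100 splits of the arrays of each tissue into strains of the same sizes, the real split included. For each result below only the real split gave as many probe sets, so chance can be excluded for single contrasts. The other splits had a median of 0 calls, which nearly fixed their 0 over all 4 tissues. For pairs of tissues, equal strain effects were not tested. For graded probe sets the other splits all gave 0. Whether the 2 contrasts overlap by chance stays open, as independent lists gave more in each tissue. For aorta the real value and the highest of the other splits were 3513 against 482 for BPH and BPN, 3971 against 1 for BPL and BPN, 4231 against 2 for BPH and BPL, and 102 against 0 for graded probe sets. For heart they were 2695 against 1652 for BPH and BPN, 3586 against 35 for BPL and BPN, 3288 against 1483 for BPH and BPL, and 111 against 0 for graded probe sets. For kidney they were 2706 against 168 for BPH and BPN, 2396 against 474 for BPL and BPN, 2429 against 396 for BPH and BPL, and 61 against 0 for graded probe sets. For liver they were 2739 against 8 for BPH and BPN, 2866 against 1 for BPL and BPN, 2213 against 2 for BPH and BPL, and 62 against 0 for graded probe sets. Over all 4 tissues they were 253, 218 and 273, each against 0, in that order. For the pairs of tissues they were 2798 against 440 for aorta and heart, 3484 against 410 for aorta and kidney, 4120 against 257 for aorta and liver, 884 against 174 for heart and kidney, 1192 against 141 for heart and liver, and 1019 against 49 for kidney and liver.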

How the results depend on the processing

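Fits without the 3 kidney arrays with adrenal transcripts, with marker levels as covariates, and jointly without aorta were chosen only after the result was seen, and the other tests were planned. Of 670 counts of probe sets with 1 array left out, 669 stayed within 1.5-fold, and median centring, renewed quantile normalization and a fit of the 2 strains compared kept every such count so. Counts of called list members were less stable: 335 of 3567 moved further with 1 array left out, and of 216 each 4 with median centring, 7 with quantile normalization, 31 in the fit of 2 strains, 78 in the joint fit, 32 with only the more abundant probe sets, 23 with a trended and robust variance, 15 with array weights, 7 with 1 probe set per gene and 18 with the mean of all probe sets of a gene. Marker covariates moved 46 of 153 and leaving out the 3 adrenal arrays 15 of 57. Of the values of named genes, calls were lost in 165 of 4433 with 1 array left out, 28 of 266 in the joint fit, 12 of 266 in the fit of 2 strains and 13 of 197 with marker covariates. The split into higher and lower moved with scaling: the share higher was 44.4% for BPL against BPN in heart (37.9% after median centring, 49.2% after quantile normalization), 49.7% in aorta (43.2%, 48.3%) and 51.5% in kidney (58.2%, 49.5%), and 49.7% for BPH against BPL in kidney (41.6%, 50.4%). Without 1 array the counts for BPH against BPN, BPL against BPN and BPH against BPL ran from 2808 to 3726, 3136 to 4143 and 3755 to 4472 in aorta, 2189 to 2880, 2908 to 3675 and 2749 to 3302 in heart, 2185 to 2732, 1840 to 2481 and 1936 to 2548 in kidney, and 2151 to 2862, 2340 to 2874 and 1880 to 2291 in liver. Graded counts ran from 67 (without aorta BPN replicate 13) to 109 (without aorta BPL replicate 21) in aorta, 77 to 108 in heart, 45 to 59 in kidney and 48 to 62 in liver. The counts over all 4 tissues ran from 235 to 257, 198 to 221 and 248 to 280, and those of the pairs of tissues from 2475 to 3208, 3038 to 3958, 3668 to 4517, 774 to 888, 1051 to 1206 and 887 to 1023, in the order aorta and heart, aorta and kidney, aorta and liver, heart and kidney, heart and liver, kidney and liver.

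The joint fit of all 12 groups, which shares 1 spread per probe set among tissues, gave 7152, 7431 and 7890 in aorta, 1530, 1741 and 1832 in heart, and graded counts of 270 in aorta, 41 in heart and 30 in kidney. With 1 probe set per gene, fewer being tested, BPH against BPL gave 2715 in aorta, and the counts over all 4 tissues were 156, 137 and 178. The direction reversed there for Spon1 in heart (-1.278), Smim14 in heart (0.111 against BPN, 0.151 against BPL), Atp5g1 in heart (-0.093), Folh1 in kidney (-0.979), Zmynd8 in liver (-0.398) and Arsk (3.436 in aorta, 0.178 in heart, 0.435 in kidney, 0.129 in liver), because another probe set was read. The graded count of kidney was 93 with only probe sets above the median mean, 93 with trend and robust, and 31 without the 3 adrenal arrays, and for the first 2 of these the cause was not tested. Marker covariates left 1194 for BPL against BPN, 1014 for BPH against BPL and 28 graded in heart, where they also widened the errors. Array weights gave 2173 for heart and kidney, 2865 for heart and liver and 2146 for kidney and liver, and the cause was not tested.

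With replicate number as a random block the last 3 were 1699, 2323 and 1870 (consensus correlation 0.00589), and 1674, 2287 and 1850 in the joint fit without aorta and without a block, so leaving out aorta made the shift. A replicate block kept 12 of 12 counts of probe sets within 1.5-fold, but moved 18 of 168 counts of list members and ended 7 calls of named genes, and same-numbered arrays correlated by a mean of -0.004 in heart, -0.034 in kidney and 0.044 in liver. Between tissues of 1 strain the same-numbered arrays correlated by a mean of 0.11 for kidney and liver of BPH (3 of 5 pairs over 0.1, other pairs -0.028), 0.081 for those of BPL and -0.044 to 0.056 for the rest, so a shared animal is not excluded. Of 216 list tests 64 were called with the preset correlation. With an estimated correlation 63 of these were lost, the 1 kept being extracellular matrix in aorta of BPL against BPN. The rotation test fry kept 51 of the 64, lost 13 and called 30 others. The number of arrays limits the precision.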

Other observations

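The genes of the first 2 paragraphs were chosen only after the result was seen, while the tests of neighbouring genes and of strain order were written down before their values were seen. BPL liver combined higher cholesterol synthesis genes with lower fatty acid synthesis genes relative to BPN. Of 15 cholesterol genes 7 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00929, and 0.545 with an estimated correlation), among them Idi1 (0.63 ± 0.08, adjusted p = 2.32e-05), Nsdhl (0.57 ± 0.11, adjusted p = 0.00167) and the regulator Srebf2 (0.32 ± 0.08, adjusted p = 0.0199). Of 15 fatty acid synthesis genes 0 rose and 7 fell (0 and 8 adjusted over the list alone, camera adjusted p = 3.07e-05, and 0.386 with an estimated correlation), with Thrsp (-1.99 ± 0.20, adjusted p = 1.53e-06) and Fasn (-1.09 ± 0.16, adjusted p = 0.000153). Of 16 genes of fatty acid oxidation and ketogenesis 5 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00986, and 0.545 with an estimated correlation), with Vnn1 (1.26 ± 0.28, adjusted p = 0.00744). Of 19 acute phase genes 1 rose and 7 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.00615, and 0.545 with an estimated correlation), with Saa3 (-1.65 ± 0.18, adjusted p = 4.23e-06), Apcs (-1.48 ± 0.10, adjusted p = 4.14e-09) and the iron hormone Hamp (-0.89 ± 0.15, adjusted p = 0.000406). The class I gene H2-K1 rose (1.17 ± 0.08, adjusted p = 1.13e-08) while 8 of 16 antigen presentation genes fell (camera adjusted p = 6.26e-05, and 0.386 with an estimated correlation).

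BPL kidney, with 4 arrays, showed the lipoxygenases Alox15 (2.94 ± 0.12, adjusted p = 3.92e-11) and Alox12 (1.23 ± 0.11, adjusted p = 1.17e-06) and the neuropeptide Npy (2.57 ± 0.12, adjusted p = 3.31e-10) above BPN. The injury markers Havcr1 (0.72 ± 0.12, adjusted p = 0.000721) and Lcn2 (0.89 ± 0.17, adjusted p = 0.00382) rose, and the aldosterone-responsive kinase Sgk1 (-0.78 ± 0.14, adjusted p = 0.00201) fell. In BPL aorta the inducible cyclooxygenase Ptgs2 (-2.76 ± 0.37, adjusted p = 6.77e-06), the pericyte regulator Rgs5 (-1.30 ± 0.17, adjusted p = 5.44e-06) and Npr3 (-1.20 ± 0.11, adjusted p = 8.48e-09) fell and the vasopressin receptor Avpr1a (1.31 ± 0.20, adjusted p = 4.18e-05) rose.

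A hypothesis was that genes differing between BPH and BPN in all 4 tissues lie next to each other more often than random genes, as inherited blocks might produce. Of the 179 genes, 24 had another of them as the next measured gene, against a median of 2 and a highest value of 15 in 10000 random sets from 19080 genes placed in assembly GRCm38.p6. The runs held H2-Ab1, H2-Aa and H2-Eb1 on chromosome 17 and Paip1, 4833420G17Rik and Tmem267 on chromosome 13, with pairs such as Abhd14a and Abhd14b or Prxl2c and Ctsl. The result fits the hypothesis, and probes shared by neighbouring paralogs were not tested as another source.

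A second hypothesis was that expression is ordered with strain pressure, so that BPN lies between the others more often than BPH or BPL does. This held in 1 of 4 tissues, heart, with 111 probe sets against 77 and 71. With BPN, BPH or BPL between, the counts were 102, 142 and 143 in aorta, 61, 81 and 53 in kidney and 62, 72 and 45 in liver. The hypothesis was not borne out but stays open, as the counts have no spread. In aorta contrasts with BPN were less precise (median error 0.124 against 0.104).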
